A study of Arabidopsis thaliana with 32 samples.

How the data were processed

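Expression was measured in whole rosettes of Arabidopsis thaliana on Affymetrix ATH1 arrays, which read each transcript with a set of short oligonucleotides (a probe set). Per the labels, 4-week-old plants of the accession Col-0 and of the mutant edr1, grown at 23 °C with 9 h days, were inoculated with the powdery mildew fungus Golovinomyces cichoracearum and harvested at 0, 18, 36 or 96 h. Each of the 32 arrays holds a pool of 4 rosettes, and each of the 8 combinations of genotype and time has 4 arrays. No mock-inoculated plants were analysed here, so a change since 0 h holds the effects of inoculation, of the hour of harvest and of plant age together. The labels do not say whether the pools of a group came from separate sowings or inoculations, so p-values measure the spread between these pools.

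The deposited table holds log2 signals, 1 per probe set and array. The scale was read from the values, which ran from -5.25 to 14.46, and from the hybridisation controls, whose means rose from 7.92 for bioB to 9.58 for bioC, 11.25 for bioD and 13.32 for cre. Per the submitters' processing notes, MAS5 and GCRMA were used; which of them made the deposited values, and in which version, is not given in the sources used here. The arrays had not been equalised: the median over the probe sets kept ran from 7.56 to 8.68 between arrays. Arrays have no read depth, and their number limits the precision.

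Of 22810 probe sets, 64 controls were left out and 2 of the remaining 22746 had a missing value. A probe set was kept when its 4th highest value lay above the 40th percentile of all values, 5.81, which left 14892. The plan written before the data were examined took the deposited values as the main setting. Because the arrays turned out not to be equalised, quantile normalization of the probe sets kept became the main setting, a choice made before any test was run. The deposited values and a shift of each array to a common median were kept as alternatives. Quantile normalization gave many more differences between genotypes than the deposited values did, so both counts are given for each comparison. On the deposited values the median of all probe sets was shifted by 0.47 at 18 h, 0.41 at 36 h and 0.15 at 96 h in Col-0 against 0 h, by 0.50, 0.65 and 0.40 in edr1, and by -0.12, -0.09, 0.11 and 0.13 between edr1 and Col-0 at 0, 18, 36 and 96 h. All changes from the main setting are therefore relative to the bulk of the transcripts.

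A mean per group was fitted to all 32 arrays with limma 3.58.1 in R 4.3.3, with moderated variances (eBayes). Contrasts gave edr1 against Col-0 at each of the 4 times, each later time against 0 h within each genotype, and the interaction of genotype and time against 0 h. P-values were adjusted by the Benjamini-Hochberg method within each contrast over 14892 probe sets, and a difference was called at an adjusted p below 0.05. Values are log2 differences with the standard error (SE) of the fit, and group means with the standard deviation (SD) over 4 arrays. The procedure was tested on simulated data for edr1 against Col-0 at 18 h over 14892 probe sets with 200 changed: it recovered 96% of those changed by 1 log2 unit and 99% of those changed by 2, and 10 of 205 calls (4.88%) were false. The simulated probe sets were independent of each other, with the same spread in all groups and a uniform shift per array. The real arrays need not be so, and these rates are therefore not error rates of the real calls.

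Genes were named only through the platform's annotation, which lists 14016 of the probe sets, 13513 with 1 gene and 503 with several; the other 8728 are unnamed here. Of the 13513, 13436 matched a current gene record and took its symbol. Of the probe sets kept, 8078 (54.2%) had 1 gene, for 7957 genes. EDR1 itself and most of the best known defence genes are among those with no named probe set, so they were not analysed here. The rule for genes named in the text was fixed before the data were examined. Per contrast it took the 8 largest rises and 8 largest falls among called single-gene probe sets whose 4 arrays in one group did not overlap the 4 in the other, or the 4 largest each way for an interaction. It added up to 4 members of each gene list described and 13 genes in every case, of which 1, PDF1.2, had a named probe set.

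Gene lists, 23 with 401 members, were likewise fixed beforehand, covering defence hormones, WRKY factors, immune receptors, secretion, redox, cold response, photosynthesis, the clock, glucosinolates, flavonoids, auxin and markers of other tissues. A member was used where its locus had a kept, single-gene probe set and the reference gave it the symbol written for it: 46 had a named probe set and 37 were used. The 8 lists with at least 3 such members were tested in each of the 13 contrasts with limma's camera at a preset correlation between genes of 0.01, adjusted over the 8 lists of a contrast. The minimum of 3 members was set once coverage was known. Members that share a symbol stem, such as PDF1.2 and PDF1.2b or COR15A and COR15B, were counted as separate genes. The preset correlation thus treats them as nearly independent. Estimated correlations and fry, which tests the list alone, were alternatives. Of 104 tests, 18 were called with the preset correlation and 0 with the estimated one; fry called 43. Another 28 lists were chosen after the data were seen: families of at least 6 genes sharing a symbol stem, genes encoded in the plastid, heat shock and chaperone genes, and berberine bridge enzyme-like genes.

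Alternatives were the deposited values, the median shift, no filter and a stricter filter, array weights, a trended robust prior, a fit of only the groups compared, separate variances, the replicate number as a block, and each array left out in turn. Splits of the arrays of each contrast into other groups of the same sizes were also counted. Array quality was compared between groups with two-sided exact permutation tests, 40 in all. Correlations between arrays of one group ran from 0.9767 to 0.9905, and no pair within a group shared more than 0.255% of its quantile-normalized values exactly. Pairs from different groups were not compared for identical values. All 32 were counted as separate samples.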

Results

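Transcript levels were measured on 32 arrays of whole rosettes, from Col-0 and from edr1, a mutant known for enhanced resistance to powdery mildew. Plants of both genotypes were sampled at 0, 18, 36 and 96 h after inoculation, with 4 arrays per genotype and time and 4 rosettes pooled per array. The study asked how the transcriptional response to the fungus differs between the genotypes. Signals are log2 values, quantile normalized here, and 14892 probe sets entered every test. Differences are given as log2 values with the SE of the fit, n = 4 arrays per group.

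Time of harvest separated the arrays most. The first principal component held 63.4% of the variance and placed the 18 h and 36 h arrays opposite those of 0 h and 96 h: group means were 43.32 and 58.52 in Col-0 at 18 and 36 h, against -48.75 at 0 h and -57.65 at 96 h. In edr1 the corresponding means were 45.60, 65.20, -53.35 and -52.92. The second component, with 14.6%, ran from -39.12 in Col-0 at 0 h to 33.98 at 96 h. Array medians of the deposited values were higher at 18 h and 36 h than at 0 h, by 0.52 and 0.44 in Col-0 and by 0.56 and 0.69 in edr1 (two-sided exact permutation p = 0.0286 each, the smallest possible, adjusted p = 0.191 over 40 tests).

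**Figure D1:**
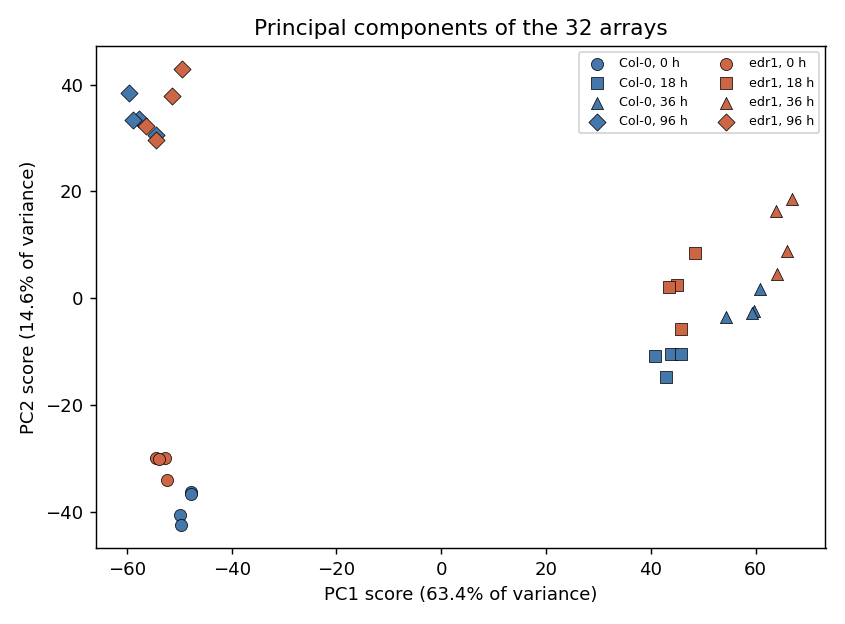
Each point is 1 of the 32 arrays, placed by its scores on the first (63.4% of variance) and second (14.6%) principal components; colour gives the genotype and shape the hours after inoculation. The 18 h and 36 h arrays lie at positive scores of the first component and the 0 h and 96 h arrays at negative scores, in both genotypes.

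EDR1, the gene altered in the mutant, has no named probe set and was not analysed here, so the genotype labels could not be checked on it. Of the 13 genes to be named in every comparison, PDF1.2, a plant defensin gene induced by ethylene and jasmonate, was the 1 that could be followed. Its mean signal in Col-0 was 6.10, 4.31, 4.45 and 4.85 at 0, 18, 36 and 96 h, and in edr1 7.32, 6.06, 6.64 and 6.26.

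At 0 h UGT76B1 exceeded its Col-0 level most among the named genes higher in edr1. This gene, which encodes a glucosyltransferase that limits salicylic acid-type immunity, was 2.86 ± 0.80 higher (5.32 ± 0.83 against 2.46 ± 1.62, mean ± SD, n = 4, both under the filter value of 5.81), and the chitinase-family gene CHI 1.98 ± 0.46 higher (8.44 ± 0.60 against 6.46). AT5G48570, an FK506-binding isomerase of the heat stress response, differed by 1.41 ± 0.15. AT1G13470 was higher by 1.57, AT3G49340 by 1.5, AT2G44380 by 1.37, AT3G28540 by 1.3 and the peroxidase gene AT4G36430 by 1.27. Limma's adjusted p for these 8 genes ran from 1.8e-06 to 0.037. Genes lower in edr1 differed less: the transcription factor gene BZIP61 differed by -1.02 ± 0.12 (adjusted p = 1.2e-05), AT2G07674 by -1.02, AT2G44430 by -0.97, AT1G65000 by -0.94, AT1G75230 by -0.91, AT3G66652 by -0.88, AT1G61420 by -0.83 and AT5G01110 by -0.80. The Col-0 means of AT3G49340 and AT4G36430 and, apart from BZIP61 and AT1G75230, the edr1 means of the lower genes were under 5.81 as well, so the size of these differences is uncertain.

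Among the 4 measured WRKY factors at 0 h, WRKY53 was higher by 0.99 ± 0.21 (adjusted p = 0.011) and the other 3 did not pass; the list missed the threshold (camera adjusted p = 0.0855). COR15B, which encodes a cold-regulated chloroplast protein, was the 1 called member of the 3 in the cold response list, at -0.65 ± 0.19, with 2 called when adjusted over the list alone and a list adjusted p of 0.0855. PDF1.2 stood at 1.21 ± 0.64 (adjusted p = 0.27) and PDF1.2b at 1.91 ± 0.84 (adjusted p = 0.18). In all, 705 probe sets were called at 0 h, 354 higher and 351 lower in edr1, of which 49 and 8 reached 2-fold. On the deposited values the count was 31 (15 higher and 16 lower), without Col-0 replicate 2 or 4 it was 409 or 226, and without edr1 replicate 1, 3 or 4 it was 311, 392 or 397. It was 233 with array weights, 44 when only the groups compared were fitted and 0 with separate variances, where 3187 had an unadjusted p under 0.05 in the limma fit.

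AT4G16260, a beta-glucanase gene, exceeded its Col-0 level most among the named genes at 18 h. It was 3.60 ± 0.62 higher in edr1 (8.49 ± 1.2 against 4.89 in Col-0), the osmotin gene OSM34 also higher (7.46 ± 0.96 against 4.34 ± 1.9, adjusted p = 0.0064) and CHI 2.96 ± 0.46 higher. AT3G23550, a multidrug efflux family gene, was up by 2.7, RING1, a ubiquitin ligase gene, by 2.16 ± 0.28, CCOAMT, of the caffeoyl-CoA methyltransferase family, by 2.04, AT4G00700 by 2.03 and AT1G13470 by 2.00. Apart from AT3G23550 and RING1, these genes had Col-0 means under the filter value of 5.81, so the size of the difference is uncertain. Adjusted p for these 8 genes lay between 1e-04 and 0.0064. The genes lower in edr1 were AT5G66740 at -2.47, AT4G16880 at -2.19, AT3G46370 at -1.98, AT4G25780 at -1.57 ± 0.23, AT1G77960 at -1.54, the subtilase gene AT5G59130 at -1.46, AT3G17640 at -1.36 and AT5G45960 at -1.24. Of these, all but AT4G25780 (6.23 against 7.80) had both group means under the filter value of 5.81, where array signals are least certain.

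Several gene lists were higher in edr1 at 18 h. Of the 4 WRKY factors, WRKY53 was up by 1.23 ± 0.21 and WRKY6 by 0.67 ± 0.20, with 3 called when adjusted over the list alone; the list gave a camera adjusted p of 0.00247, and an adjusted p of 0.121 with an estimated correlation. In the ethylene and jasmonate defence list PDF1.2b was up by 2.73 ± 0.84 (adjusted p = 0.044), 3 of 4 were called when adjusted over the list alone, and the list adjusted p was 0.0143 (adjusted p = 0.121 with an estimated correlation). Its other members were PDF1.2 at 1.74 ± 0.64, THI2.1 at 0.48 and EIN3 at 0.19. The PDF1.2b values overlapped between genotypes, with an SD of 2.11 in edr1, and its probe set can cross-hybridise with related sequences. The Col-0 means of PDF1.2b (3.93), PDF1.2 (4.31) and WRKY6 (5.45) were under the filter value of 5.81. The size of these differences is therefore uncertain. Of 3 secretion and protein folding genes the stress regulator BZIP60 was up by 0.32 ± 0.09, with 2 called when adjusted over the list alone, and that list had an adjusted p of 0.0237 (adjusted p = 0.161 with an estimated correlation). The immune receptor list did not pass (adjusted p = 0.156), though PUB24, a ubiquitin ligase gene, was higher by 0.62 ± 0.17.

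At 18 h 1118 probe sets were called, 614 higher and 504 lower, with 168 and 20 of at least 2-fold. The deposited values gave 248 (193 higher and 55 lower), the median shift 1073 (693 and 380), array weights 2172 and separate variances 1. Leaving out Col-0 replicate 1 or 2 gave 693 or 564, and leaving out edr1 replicate 1 or 2 gave 525 or 609.

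**Figure D2:**
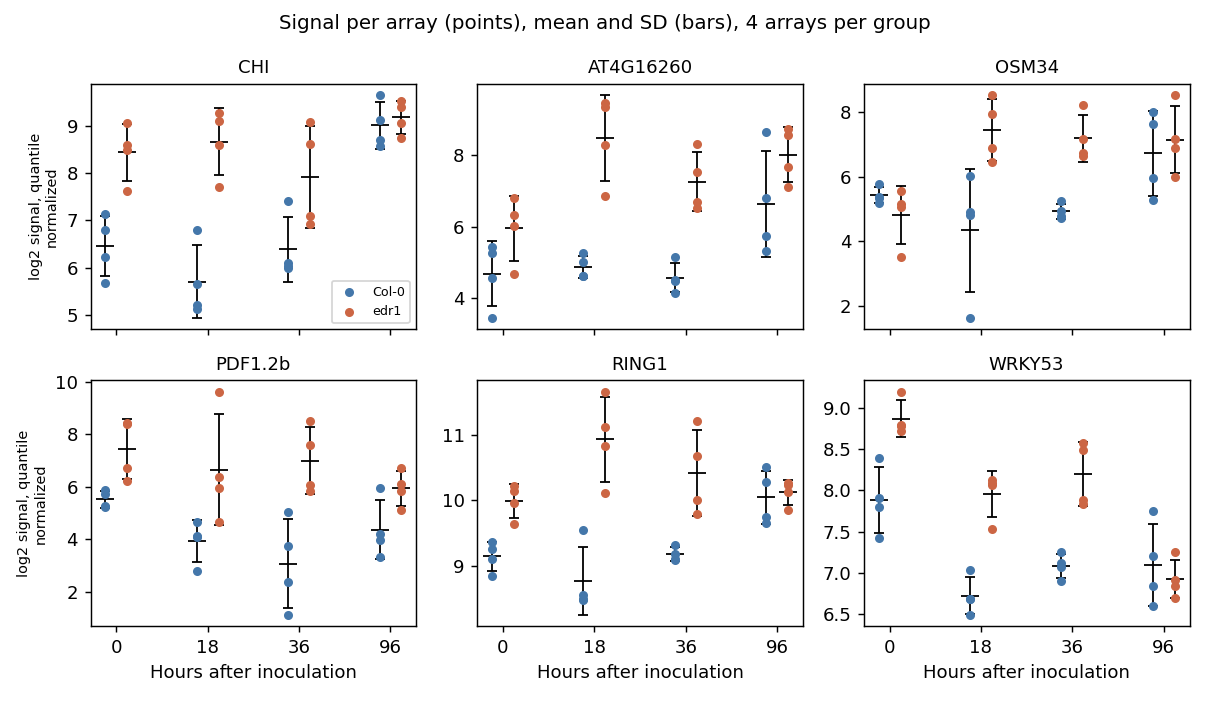
Quantile-normalized log2 signal of 6 genes against hours after inoculation; points are single arrays, horizontal marks the mean and bars the SD of 4 arrays per group, blue for Col-0 and orange for edr1. At 18 h AT4G16260 had a mean of 8.49 in edr1 against 4.89 in Col-0, and WRKY53 a mean of 7.95 against 6.73.

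The genotypes differed in the largest number of probe sets at 36 h. PDF1.2b was 3.93 ± 0.84 higher in edr1 (7 ± 1.27 against 3.07 ± 1.7), read by a probe set that can cross-hybridise with related sequences, and PDF1.2 was 2.20 ± 0.64 higher (adjusted p = 0.018). AT4G16260 was up by 2.68, AT3G13950 by 2.63, AT3G23550 by 2.49, OSM34 by 2.27, the carboxylesterase-like gene AT1G68620 by 2.05, the berberine bridge enzyme-like gene AT1G26390 by 1.98 and AT1G72060, a protease inhibitor gene, by 1.93 ± 0.33. Apart from AT3G23550 and AT1G72060, these genes had Col-0 means under the filter value of 5.81, so the size of the difference is uncertain. The genes lower in edr1 were AT4G16880 at -2.64, the anthocyanin glucosyltransferase gene AT4G14090 at -1.94, AT5G66740 at -1.82, AT1G23340 at -1.35, AT5G55570 at -1.34, AT3G51750 at -1.31, JMT, the jasmonate methyltransferase gene, at -1.26 ± 0.38, and AT1G73600, a phosphoethanolamine methyltransferase gene, at -1.21 ± 0.18. All of these lower genes but AT1G73600 (6.48 against 7.69) had both group means under the filter value of 5.81.

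By list, 3 of 4 WRKY factors were higher in edr1 than in Col-0 at 36 h (WRKY53 by 1.11 ± 0.21, WRKY6 by 0.58 and WRKY22 by 0.39) and 4 when adjusted over the list alone, with a list adjusted p of 0.00427 (adjusted p = 0.0966 with an estimated correlation). Of 4 ethylene and jasmonate defence genes 2, PDF1.2 and PDF1.2b, were higher in edr1, and 3 when adjusted over the list alone. That list had an adjusted p of 0.00468 (adjusted p = 0.0966 with an estimated correlation). PUB24 was higher in edr1 by 0.83 ± 0.17, the 1 called of 3 immune signalling genes, with 2 called when adjusted over the list alone, and that list passed too (adjusted p = 0.00939, and adjusted p = 0.0966 with an estimated correlation). Of 4 auxin response genes 3 were higher in edr1, WES1 by 0.80 ± 0.19, GH3.3 by 0.83 and IAA29 by 0.56, the same number as when adjusted over the list alone (list adjusted p = 0.00939, and adjusted p = 0.127 with an estimated correlation). Photosynthesis genes were lower in edr1 than in Col-0, 3 of 5 both over all probe sets and adjusted over the list alone: SBPASE at -0.47, PRK at -0.38 ± 0.06 and RCA at -0.24 ± 0.05, all enzymes of carbon fixation or its activation, while LHCB4.1 stood at -0.08 and PSAN at 0.02; the list median was -0.24, and -0.13 on the deposited values (list adjusted p = 0.00427, and adjusted p = 0.0966 with an estimated correlation). COR15A and COR15B were lower by -0.81 and -0.70 in a cold response list that did not pass (adjusted p = 0.247). GRX480, which answers salicylic acid, was higher by 0.97 ± 0.33 (adjusted p = 0.045), and SAG101, of the same list, stood at 0.42 ± 0.16 (adjusted p = 0.082). Both group means of GRX480 (5.67 in edr1 and 4.7 in Col-0) were under the filter value of 5.81. So were the Col-0 means of WRKY6 (5.44) and GH3.3 (5.23) and the edr1 mean of COR15B (5.72). The size of these differences is therefore uncertain.

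At this time 2351 probe sets were called, 1022 higher and 1329 lower, with 180 and 34 of at least 2-fold. The deposited values gave 634 with a different balance, 548 higher and 86 lower, and separate variances gave 25. Without Col-0 replicate 4 the count was 1404, and without edr1 replicate 1 or 3 it was 1473 or 1305.

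**Figure D3:**
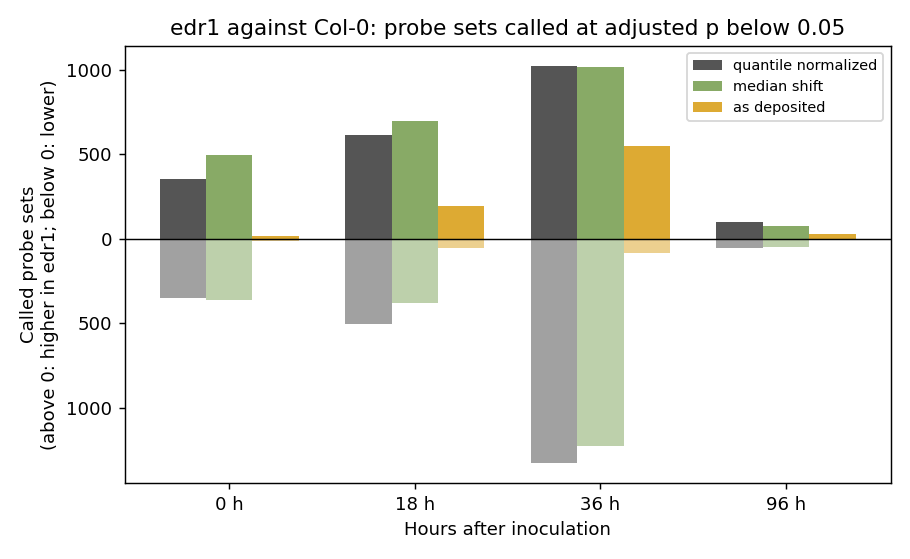
Number of probe sets called in edr1 against Col-0 (vertical axis) at each time after inoculation (horizontal axis); solid bars above 0 are higher in edr1 and paler bars below 0 are lower, and colours are the 3 scalings of the arrays. After quantile normalization 705, 1118, 2351 and 154 probe sets were called at 0, 18, 36 and 96 h, against 31, 248, 634 and 37 on the deposited values.

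At 96 h the genotypes differed in fewer probe sets than at 36 h. AT4G19430 was 2.01 ± 0.30 higher in edr1 (8.97 ± 0.41 against 6.96), AT2G19970 1.88 ± 0.33 higher, the peroxidase gene AT2G37130 1.51 ± 0.18 higher (adjusted p = 2.3e-05) and EXLA1, an expansin-like gene, 1.42 ± 0.25 higher. AT1G33055 was up by 1.24, NAI1, a transcription factor gene needed for ER bodies, by 0.93, AT1G05575 by 0.93 and AT1G19380 by 0.92. For AT2G19970, AT1G33055, NAI1 and AT1G05575 the Col-0 mean was under 5.81, so the size of the difference is uncertain. AT5G26270 was lower by -4.38 ± 0.91 (6.43 against 10.81), but this probe set took either a low value (5.28 to 6.78) or a high one (10.66 to 11.20): it was high in 1, 0, 2 and 4 of 4 Col-0 arrays at 0, 18, 36 and 96 h and in 0 of 16 edr1 arrays, so its -4.38 need not be a difference in expression. COR15B was lower by -1.06 ± 0.19, AT4G17215 by -1.05, COR15A by -1.03 ± 0.23, AT1G06100 by -0.98, AT4G15810 by -0.90, AT4G11000 by -0.83 and AT1G21580 by -0.79. A second probe set of AT4G15810 differed by 0.24 and one of AT1G21580 by -0.06, so these last probe sets do not speak for the whole gene.

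Cold response genes were lower as a list in edr1 at 96 h (adjusted p = 0.000779, and adjusted p = 0.0537 with an estimated correlation). The 2 of 3 called, as many as when adjusted over the list alone, were COR15A and COR15B. The third, COR47, stood at -0.07, so the list call rests on COR15A and COR15B. The ethylene and jasmonate defence list passed (adjusted p = 0.0071, and adjusted p = 0.0839 with an estimated correlation). Of its members 0 were called over all probe sets and 1 when adjusted over the list alone. PDF1.2b was at 1.58 ± 0.84, PDF1.2 at 1.41 ± 0.64 and THI2.1 at 1.22 ± 0.36. The Col-0 means of PDF1.2b (4.37) and PDF1.2 (4.85) were under the filter value of 5.81, so the size of both differences is uncertain. The auxin list passed likewise with 0 called (adjusted p = 0.0258, and adjusted p = 0.262 with an estimated correlation), its members being GH3.3 at 0.76 ± 0.29, IAA29 at 0.43 ± 0.19, WES1 at 0.22 and EXPA8 at 0.18. The Col-0 mean of GH3.3 was 5.22, also under the filter value. WRKY53 stood at -0.17 ± 0.21 (adjusted p = 0.79). Of 154 probe sets called at 96 h, 96 were higher and 58 lower, 17 and 9 of at least 2-fold; the deposited values gave 37 (27 and 10), array weights 243, no filter 69, a fit of only the groups compared 4 and separate variances 1. Without Col-0 replicate 1 the count was 97, and without edr1 replicate 1 or 3 it was 64 in each case.

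Across times, 385 probe sets were higher in edr1 at both 18 h and 36 h, where 42.1 would be shared by independent lists, and 284 were lower at both, against 45. The overlap of 0 h with 18 h was 90 higher probe sets against 14.6 and 44 lower against 11.9, and that of 0 h with 36 h 93 higher against 24.3 but 46 lower against 31.3. These contrasts share no arrays. There were 56 probe sets higher at 0, 18 and 36 h, and 2 at all 4 times. Of the 96 probe sets higher at 96 h 42 were also higher at 36 h (6.59 for independent lists) and 21 at 18 h (3.96), and of the 58 lower 14 (5.18) and 4 (1.96) were also lower.

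From 0 to 18 h both genotypes changed most of the measured transcripts, and COR27, COR15A and GI were among the largest changes of named genes. COR27, a cold- and clock-regulated gene, rose by 5.36 ± 0.28 in Col-0 and by 6.05 ± 0.28 in edr1, and its relative AT4G33980 by 7.45 ± 0.70 and 7.54 ± 0.70. AT1G17665, AT2G38465, AT3G20340 and AT2G23910 also rose in both, by 4.52, 4.17, 4.12 and 4.04 in Col-0 and by 3.85, 4.38, 4.31 and 4.54 in edr1. Col-0 added AT1G49200 at 3.63 and AT5G58570 at 3.52; edr1 added AT1G30700, a berberine bridge enzyme-like gene, at 4.23 ± 1.06 and AT1G26665 at 3.91. GI, an evening clock gene, was at -5.19 ± 0.36 in Col-0 and -5.78 ± 0.36 in edr1, COR15A at -5.33 and -5.40, and AT1G13650 at -6.57 and -8.70. AT1G73600 was at -4.90 and -5.48, AT4G16880 at -4.36 and -6.73 and AT5G59130 at -4.28 and -5.59. Also among the largest falls were the thionin gene THI2.2 at -5.03 and the lectin-like gene AT5G03350 at -4.16 in Col-0, and AT2G27420 at -5.87 and AT5G66740 at -5.27 in edr1. Apart from AT1G49200, AT5G58570 and AT1G26665 these rises started from means under the filter value of 5.81, and apart from COR15A, AT1G73600 and AT5G03350 these falls ended under it, so their sizes are uncertain.

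All 5 photosynthesis genes fell at 18 h in both genotypes, also when adjusted over the list alone: SBPASE was at -0.85 ± 0.09 in Col-0 and -1.17 ± 0.09 in edr1, and PSAN at -0.41 and -0.48. The size of the fall depends on scaling, with list medians of -0.41 and -0.36, against -0.94 and -1.03 with the median shift. The list had an adjusted p of 0.0300 in Col-0 and 0.0242 in edr1 (adjusted p = 0.256 and 0.359 with an estimated correlation). Of 3 cold response genes COR15A and COR15B fell, the latter at -4.02 and -3.66, and COR47 stood at -0.04 and 0.06; 2 were called when adjusted over the list alone, and the list passed in Col-0 (adjusted p = 0.0405, and adjusted p = 0.256 with an estimated correlation) but not in edr1 (adjusted p = 0.0810), a difference not called between genotypes (interaction adjusted p = 0.555). BIK1, which encodes a cytoplasmic kinase acting downstream of immune receptors, rose by 1.08 ± 0.12 and 0.93 ± 0.12. GRX480 was at -2.12 and -1.55 and the stress zinc finger gene STZ at -2.23 and -1.90, whereas the ethylene signalling gene EIN3 rose by 0.55 and 0.92. PDF1.2 was at -1.79 ± 0.64 in Col-0 (adjusted p = 0.015) and -1.26 ± 0.64 in edr1 (adjusted p = 0.081). At 18 h the means of COR15B (5.52 in Col-0 and 5.23 in edr1) and GRX480 (4.82 and 5.68) were under the filter value of 5.81. So was that of PDF1.2 in Col-0 (4.31), and the sizes of these falls are uncertain. The calls numbered 9723 in Col-0 (4987 higher and 4736 lower) and 10096 in edr1 (5181 and 4915). On the deposited values, whose medians rose, the split was 8367 higher and 1589 lower in Col-0 and 8699 and 1588 in edr1. Both genotypes shared 4378 higher and 4084 lower probe sets, against 1735 and 1563 for independent lists.

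At 36 h several of the same genes were again among the largest changes. COR27 stood 6.80 ± 0.28 above its 0 h level in Col-0 and 7.53 ± 0.28 in edr1, AT4G33980 8.21 and 8.54, AT3G20340 4.64 and 5.39, AT2G23910 4.70 and 5.17, AT2G38465 5.02 and 5.08, and AT1G17665 5.27 and 4.71. Col-0 also had AT1G07050 at 4.85 and AT3G50120 at 4.37, and edr1 AT3G59350 at 4.63 and HIS1-3, a drought-inducible linker histone gene, at 4.54. AT1G13650 was at -9.02 in Col-0 and -10.59 in edr1, AT2G15020 at -7.16 and -7.97, AT3G57020 at -4.51 and -5.19 and THI2.2 at -4.38 and -5.34. In Col-0 AT3G46370 was at -5.70, AT5G35970 at -5.12, AT5G03350 at -4.78 and AT3G01060 at -4.41, and in edr1 AT4G16880 at -6.51, AT1G73600 at -5.57, AT5G43180 at -5.57 and AT2G27420 at -5.29. GI was at -3.21 and -2.84. All these rises but those of AT3G59350 and HIS1-3 started under 5.81, and all the falls but those of AT5G35970, AT5G03350, AT3G01060, AT1G73600 and, in Col-0, AT3G57020 ended under it, so neither their sizes nor a comparison with 18 h can be relied on.

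Photosynthesis genes were again lower at 36 h, 5 of 5 in each genotype and adjusted over the list alone, with PSAN at -0.92 and -0.91 and RCA at -0.42 and -0.68, and list medians of -0.42 and -0.70, against -1 and -1.35 with the median shift (list adjusted p = 0.0129 in Col-0 and 0.00406 in edr1, and adjusted p = 0.362 and 0.229 with an estimated correlation). Of the secretion genes 3 of 3 fell in each genotype, among them CRT1b, a calreticulin gene, at -1.22 ± 0.09 and -1.46 ± 0.09, though the list did not pass (adjusted p = 0.117 and 0.128) and BZIP60 went from -0.38 and -0.27 to 0.00 and 0.34 on the deposited values. The trichome regulator TRY was at -2.78 ± 0.17 and -3.11 ± 0.17, the glucosinolate pathway gene BCAT4 at -1.01 and -1.29, JMT at -2.42 and -3.78, and DFR, of anthocyanin synthesis, at -1.70 and -2.56. THI2.1, a thionin gene, rose by 1.44 and 2.16 and the guard cell regulator FMA by 0.24 and 0.45. PDF1.2 was at -1.66 ± 0.64 in Col-0 (adjusted p = 0.023) and -0.67 ± 0.64 in edr1 (adjusted p = 0.34). At 36 h the means of TRY (4.83 in Col-0 and 4.48 in edr1) and JMT (4.24 and 2.98) were under the filter value of 5.81. So were those of DFR in edr1 (4.94) and PDF1.2 in Col-0 (4.45). THI2.1 started under it (4.53 in Col-0 and 4.71 in edr1). The sizes of these changes are therefore uncertain. The calls were 10410 in Col-0 (5457 higher and 4953 lower) and 10968 in edr1 (5769 and 5199), or 7755 and 2265, and 9534 and 1840, on the deposited values. Shared probe sets were 4900 higher and 4367 lower, against 2114 and 1729 for independent lists.

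At 96 h, the same nominal hour of the day as 0 h, genes of the heat stress response were among the largest rises in both genotypes. The small heat shock protein gene AT2G29500 rose by 5.45 ± 0.41 in Col-0 and 4.31 ± 0.41 in edr1, Hop3, a co-chaperone gene, by 5.17 ± 0.17 and 4.39 ± 0.17, and AT1G53540, another small heat shock protein gene, by 4.75 and 3.97. AT2G20560, of the DnaJ family, rose by 4.29 and 3.57 and the mitochondrial small heat shock protein gene AT5G51440 by 4.23 and 4.34. UGT76B1 rose by 5.11 ± 0.80 in Col-0, along with AT5G48570 by 4.01 and AT1G21520 by 3.99; edr1 added AT4G19430 at 4.42, AT5G25450 at 3.47 and AT5G18340 at 3.25. PORB, a chlorophyll synthesis gene, fell in both, at -3.45 ± 0.10 and -3.18 ± 0.10, as did AT5G62210 at -4.46 and -4.74 and AT2G20670 at -3.98 and -3.36. In Col-0 the other large falls were AT1G50040 at -4.55, AT1G77640 at -4.00, EXLA1 at -3.80, AT4G37240 at -3.39 and the calmodulin-like gene CML38 at -3.36. In edr1 they were AT1G31690 at -3.51 (-1.55 on its second probe set), AT1G21540 at -3.49, AT3G55840 at -3.43, AT5G59330 at -3.26 and AT3G44970 at -3.19. Apart from AT5G48570, AT5G25450 and, in edr1, Hop3 and AT2G20560, these rises started from means under 5.81, and apart from PORB, AT2G20670, EXLA1 and AT4G37240 these falls ended under it, so their sizes are uncertain.

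**Figure D4:**
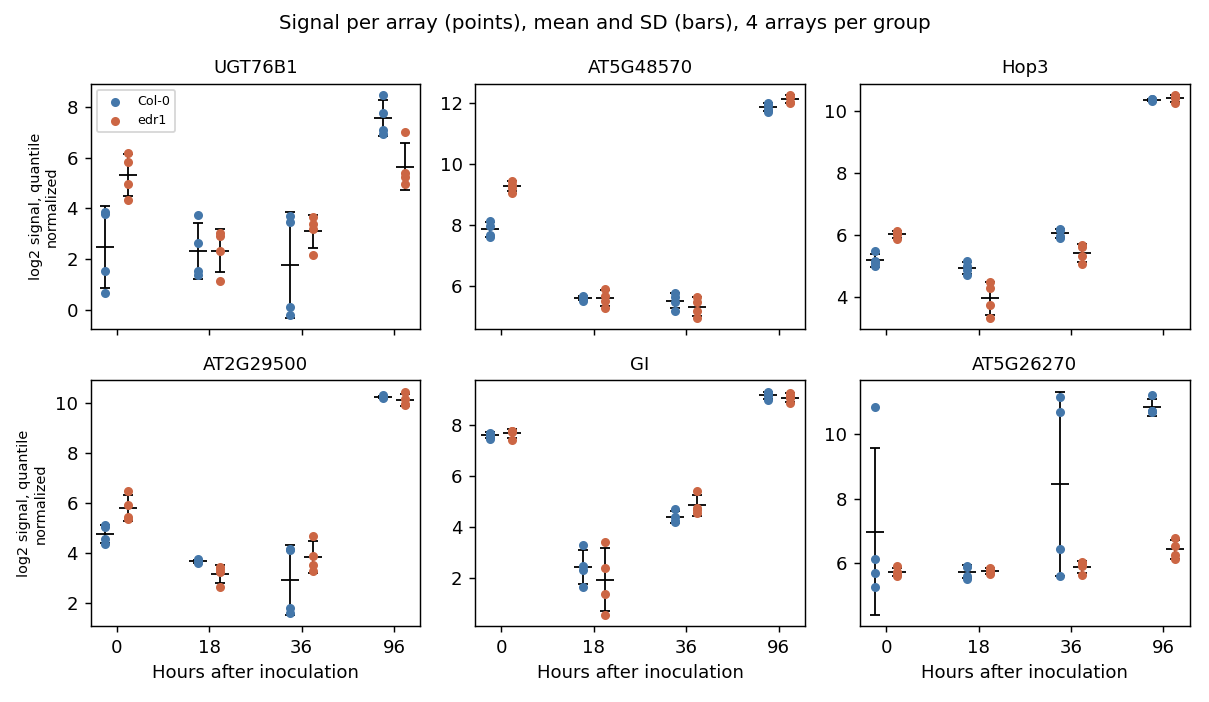
Quantile-normalized log2 signal of 6 genes against hours after inoculation; points are single arrays, horizontal marks the mean and bars the SD of 4 arrays per group, blue for Col-0 and orange for edr1. Hop3 rose from a mean of 5.18 to 10.35 in Col-0 between 0 and 96 h, and the high values of AT5G26270 are confined to 7 of 16 Col-0 arrays.

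None of the 8 planned lists passed at 96 h against 0 h in either genotype; the lowest adjusted p was 0.284 in Col-0, for photosynthesis, and 0.123 in edr1, shared by photosynthesis and the WRKY factors. Of the photosynthesis genes 4 of 5 fell in each genotype, as many as when adjusted over the list alone. Of the WRKY factors WRKY53 was at -0.78 in Col-0 and -1.94 ± 0.21 in edr1, and WRKY22 at -1.29 and -1.12. GI was at 1.58 ± 0.36 and 1.41 ± 0.36, and THI2.1 at 1.36 and 2.40. GRX480 rose by 0.94 ± 0.33 in Col-0 and stood at -0.36 ± 0.33 in edr1, a difference that did not pass (interaction adjusted p = 0.15). PDF1.2 was at -1.25 ± 0.64 and -1.06 ± 0.64 (adjusted p = 0.10 and 0.17). At 96 h WRKY22 (5.28 in Col-0 and 5.37 in edr1) and, in Col-0, PDF1.2 (4.85) had means under the filter value of 5.81. THI2.1 started under it (4.53 in Col-0 and 4.71 in edr1). The sizes of these changes are therefore uncertain. Fewer probe sets were called than at 36 h, 7956 in Col-0 (3934 higher and 4022 lower) and 7639 in edr1 (3913 and 3726), with 2841 higher and 2909 lower in both, against 1034 and 1006 for independent lists. On the deposited values the splits were 3947 higher and 1751 lower in Col-0 and 7635 and 930 in edr1, and with separate variances 5100 were called in Col-0. Within arrays, the difference between the 3' and 5' probe sets of ubiquitin, a measure of RNA quality, was lower at 96 h than at 0 h by 0.14 in Col-0 (0.31 against 0.45) and 0.17 in edr1 (0.30 against 0.47; exact p = 0.0286 each, adjusted p = 0.191).

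Whether the change since 0 h differed between genotypes was tested by the interaction. At 18 h the largest negative interactions among the named genes were AT5G66740 at -2.50 ± 0.55, Hop3 at -1.80 ± 0.24 (adjusted p = 0.00047), AT5G48570 at -1.42 ± 0.21 and AT4G33960 at -1.02 ± 0.16. AT2G16660 at 1.1, AT1G65000 at 1.00 and AT5G52530 at 0.55 went the other way. AT5G48570 and AT1G65000 had nearly equal means in edr1 and Col-0 at 18 h (5.59 and 5.60, and 7.09 and 7.04), so their interactions rest on the differences at 0 h, 1.41 and -0.94. Of 44 called probe sets 6 were positive and 38 negative, and 3 (1 and 2) on the deposited values; single arrays moved this count between 11 and 130. None of the 8 planned lists passed, the lowest adjusted p being 0.296.

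At 36 h AT5G43180 was at -3.16 ± 0.76, AT4G16880 at -2.82 ± 0.59, AT5G48570 at -1.61 ± 0.21 (adjusted p = 6.7e-05) and Hop3 at -1.47 ± 0.24, and AT2G17740 was at 1.48, AT2G45500 at 1.37, AT1G75230 at 1.33 and AT5G65300 at 1.3. For AT5G48570 most of the interaction is again the 0 h difference, with means of 5.31 in edr1 and 5.51 in Col-0 at 36 h. Photosynthesis genes had fallen further in edr1, 3 of 5 and as many adjusted over the list alone, SBPASE by -0.57 ± 0.13, PRK by -0.37 and RCA by -0.26, with a list median of -0.26 that was -0.11 on the deposited values (list adjusted p = 0.0102, and adjusted p = 0.218 with an estimated correlation). The auxin list was higher with IAA29 at 1.08 ± 0.28 the 1 called of 4 and 3 adjusted over the list alone (adjusted p = 0.00857, and adjusted p = 0.218 with an estimated correlation). The 617 called probe sets were 223 positive and 394 negative; the deposited values gave 25 (20 and 5), no filter 397 and only the groups compared 299, and without Col-0 36 h replicate 4 or edr1 36 h replicate 3 there were 334 or 307.

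At 96 h UGT76B1 had risen less in edr1 by -4.79 ± 1.13 (adjusted p = 0.028), of which 2.86 is its higher level in edr1 at 0 h, where both means were under 5.81, and AT1G13470 by -2.36, AT1G21520 by -1.96 and AT5G52810 by -1.75 ± 0.26. EXLA1 was at 1.91 ± 0.35, AT5G62360 at 1.27, AT1G01130 at 1.22 and AT1G65000 at 1.21. At 0 h AT1G13470 already differed by 1.57 and AT1G65000 by -0.94 between genotypes, which is most of their interactions. The secretion gene ATERDJ3B was at -0.59 ± 0.15 (adjusted p = 0.048), and none of the 8 planned lists passed, the lowest adjusted p being 0.0511. Here 204 probe sets were called, 91 positive and 113 negative, against 6 (4 and 2) on the deposited values, 130 with array weights, 87 with no filter and 58 with only the groups compared; single arrays moved the count between 93 and 373.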

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

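The tests of array scaling, of held-out arrays and of a lasting genotype difference at 0 h, of quantile normalization at 36 h, and of harvest day and infection at 96 h were chosen after the results were seen, and the offset from 18 h to 36 h was added after the first offset test but before its own value was seen.

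Genes higher in edr1 at 0 h form the first pattern: 49 probe sets at least 2-fold higher at 0 h, 12 of them with 1 gene, had a median difference of 1.41. On the deposited values their median was 1.34, so array scaling does not set the size of these differences. The same arrays chose the probe sets, and all probe sets shifted by only -0.12 there, so this test could hardly have failed. The number called does depend on scaling, with 705 in the main setting and 31 on the deposited values. A single pool of rosettes cannot be told apart: the median of 1.29 or more with any of the 8 arrays left out rests on arrays that also chose the genes, the medians of arrays held out of that choice ran from 0.73 to 1.7, and the probe sets called at 0 h fell from 705 to 226 without Col-0 replicate 4. A lasting genotype difference needs the same genes higher later, and 89.8% of them (44 of 49) were higher at 18 h, where 44% of all probe sets were, with 26 called; at 36 h 42 were higher and 21 called. At 96 h 20 were higher and 3 called, with a median of -0.11, and a difference in how the 2 genotypes grew stays open and untested.

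The second pattern is that 36 h held the most differences between genotypes. The median shift called 2243, which argues against quantile normalization as the cause, and 36 h also held the most on the deposited values, but with 634 (548 higher and 86 lower), so number and balance depend on scaling. An offset in time of day between the genotypes was tested against the Col-0 change from 0 h and 96 h to 18 h. There r was 0.027 (0.003 to 0.056 with an array left out), and against the same change in edr1 it was 0.216. The 36 h arrays lay beyond those of 18 h on the first principal component (58.52 against 43.32 in Col-0). An offset at 36 h need not follow this change, so the test does not decide and an offset stays open. An offset along the change from 18 h to 36 h cannot be told apart from an effect of genotype, with a mean r of 0.147 (0.061 to 0.222 over 6 splits of the Col-0 36 h arrays). Probe sets are not independent, so these r have no p here.

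Heat shock genes higher at 96 h than at 0 h are the third pattern, with all 10 measured members called in both genotypes. Scaling does not set the size of this rise, since the smaller median on the deposited values was 3.6 (edr1, with 4.34 in Col-0). All probe sets shifted there by only 0.15 in Col-0 and 0.40 in edr1, so this test could hardly have failed. In the main setting the list median was 4.12 in Col-0 and 3.22 in edr1. Growth or harvest conditions on the day and the infection cannot be told apart as causes in either genotype, because no uninoculated plants of 96 h were analysed here.

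Other splits of the arrays into groups of the same sizes were counted for each comparison. Between genotypes the real count was the highest of 35 splits at every time. It was 705 against 224 for the highest other split at 0 h, 1118 against 133 at 18 h, 2351 against 416 at 36 h and 154 against 10 at 96 h. Against 0 h the real count was likewise the highest of 35. In Col-0 it was 9723 against 3100, 10410 against 4115 and 7956 against 1245, and in edr1 10096 against 2600, 10968 against 4227 and 7639 against 743. With 35 splits 1 of 35 is the smallest share possible, and it was not corrected for the number of comparisons. Chance is thus made less likely but is not excluded. A difference between the pools other than genotype or time would pass the same test. For the interactions 100 splits were drawn. Some of them exchange most arrays between genotypes at 1 time and so add the genotype difference itself to the count. At 18 h 5 gave at least the 44 called, up to 743 in a split that exchanges all arrays at 18 h and 1 of each genotype at 0 h, so these splits leave open whether chance gives 44. At 36 h 1 did, the real one (617 against 457). At 96 h 2 did (204 against 209). The split with 209 exchanges all arrays at 0 h and 3 of 4 of each genotype at 96 h, which is close to the real split with its sign turned. Chance is thus less likely for the interactions at 36 h and 96 h, but 100 splits in the main setting do not exclude it.

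The response since 0 h differed between genotypes by the test of the interaction for 44 probe sets at 18 h, 617 at 36 h and 204 at 96 h. At 18 h these included AT2G16660 (1.1), AT1G65000 (1), AT5G52530 (0.55), AT5G66740 (-2.5), Hop3 (-1.8), AT5G48570 (-1.42) and AT4G33960 (-1.02). At 36 h they included AT2G17740 (1.48), AT2G45500 (1.37), AT1G75230 (1.33), AT5G65300 (1.3), AT5G43180 (-3.16), AT4G16880 (-2.82), AT5G48570 (-1.61) and Hop3 (-1.47). At 96 h they included EXLA1 (1.91), AT5G62360 (1.27), AT1G01130 (1.22), AT1G65000 (1.21), UGT76B1 (-4.79), AT1G13470 (-2.36), AT1G21520 (-1.96) and AT5G52810 (-1.75). As given above, the interactions of AT5G66740, Hop3, AT5G48570, AT1G65000, AT5G43180, AT4G16880, UGT76B1 and AT1G21520 rest in part on means under the filter value. Their sizes are therefore uncertain.

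Single arrays lay far from the other 3 of their group in 16 of 330 groups examined, where chance gives about 16; array measures and the genes with the largest changes were examined, and members of gene lists were not. The value is the gap to the nearest array over the range of the group, listed where it passed Dixon's 95% critical value. In edr1 at 0 h these were the actin 3' minus 5' difference (0.903, replicate 2 low), AT1G31690 (0.961, replicate 1 low), AT2G27420 (0.91, replicate 1 high) and GI (0.916, replicate 1 low). In Col-0 at 0 h they were AT1G65000 (0.89, replicate 3 high) and AT4G36430 (0.931, replicate 2 low). In Col-0 at 18 h they were AT5G03350 (0.957) and RING1 (0.935), both replicate 3 high, and at 36 h AT3G13950 (0.869, replicate 4 low) and AT5G03350 (0.836, replicate 2 high). In Col-0 at 96 h they were AT1G77640 (0.839, replicate 1 low) and AT5G26270 (0.921, replicate 1 high), and in edr1 at 96 h AT1G31690 (0.837, replicate 2 high), AT3G55840 (0.951, replicate 2 low), AT5G51440 (0.852, replicate 3 high) and COR15A (0.923, replicate 3 low).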

How the results depend on the processing

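Quantile normalization took the place of the planned deposited values after the arrays were examined, and the other scalings of the gene list tests were added after the data were seen. A gene value was counted as kept when its side of the threshold held, and its direction too where it was called in either setting. A change of sign in a value called in neither setting was thus counted as kept. Of 656 gene values, 551 were kept on the deposited values, 85 lost and 15 gained the call and 5 reversed. Kept were 630 with the median shift, 623 with array weights, 648 with a trended robust prior, 613 with no filter and 576 with only the groups compared. Separate variances kept 401 of 522, the stricter filter 389 of 397 and leaving out 1 array 5963 of 6320. Those reversed on the deposited values, none called there, were BZIP60 in Col-0 at 36 h (0.004) and in edr1 at 18 h (0.157) and 36 h (0.341), WRKY22 in edr1 at 18 h (0.243) and PUB23 in edr1 at 36 h (0.152). Counts between genotypes at 0, 18, 36 and 96 h were 31, 248, 634 and 37 on the deposited values, and the interactions at 18, 36 and 96 h gave 3, 25 and 6. No filter gave 69 at 96 h and interactions of 22, 397 and 87, and the stricter filter 113 for the interaction at 18 h. Array weights gave 233 at 0 h, 2172 at 18 h, 243 at 96 h and 130 for the interaction at 96 h. With only the groups compared, where fewer arrays estimate the variance, 44 were called at 0 h, 4 at 96 h and 22, 299 and 58 for the interactions. Separate variances gave 0, 1, 25 and 1 between genotypes and 5100 in Col-0 at 96 h. Apart from the smaller number of arrays, the cause was not tested. Gene list tests called numbered 18 of 104, 0 with an estimated correlation, 43 with fry, 28 with no filter, 31 on the deposited values and 22 with the median shift. With 1 array left out the ranges were 226 to 987, 525 to 1570, 1305 to 2623 and 64 to 149 between genotypes, and 11 to 130, 307 to 908 and 93 to 373 for the interactions. Against 0 h they were 9258 to 9547, 10005 to 10177 and 7373 to 7779 in Col-0, and 9541 to 9867, 10560 to 10734 and 6878 to 7392 in edr1. An alternative value added before taking logs was not run, because the table is already log2. Signals near the filter value of 5.81 limit what can be said of weakly expressed genes.

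Arrays of different groups share replicate numbers 1 to 4, which were not taken as a pairing, since the labels give no shared batch and not every correlation passed 0.1: same-numbered arrays had residual correlations from -0.177 to 0.299 (median 0.044, 39 of 112 over 0.1), against a median of -0.018 for other numbers, and 16 of 32 arrays correlated best with their own number. A shared batch need not lift every correlation over 0.1, so that rule does not decide against a pairing. The dap control, a transcript spiked into the samples, averaged 11.16, 11.97, 11.43 and 11.85 over the arrays numbered 1 to 4. Shared handling by number is therefore left open, and the main setting does not allow for it. A replicate block gave 945, 1346, 2652 and 227 between genotypes, 61, 777 and 307 for the interactions, and 18 list calls, as many as without it.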

Other observations

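The gene families described here, the scan for probe sets with 2 levels and the test of time of day were chosen after the values were seen.

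Heat shock and chaperone genes were chosen as a list after the values of these same arrays were seen. The p-values given for this list are therefore not independent support for it. All 10 measured of 27 rose from 0 to 96 h, with a median of 4.12 in Col-0 and 3.22 in edr1 (camera adjusted p = 5.8e-11 and 7.23e-11, and adjusted p = 6.85e-05 and 7.31e-05 with an estimated correlation). At 18 h the medians were -1.07 in Col-0 and -1.89 in edr1 and at 36 h -0.86 and -1.32, with no list call (adjusted p = 0.548, 0.138, 0.522 and 0.136). In edr1 4 of the 10 were already higher than in Col-0 at 0 h, and 7 when adjusted over the list alone, with a median of 0.58 (adjusted p = 6.61e-06, and adjusted p = 0.00405 with an estimated correlation). The interaction at 18 h was lower, with a median of -0.44 and -0.08 on the deposited values (adjusted p = 0.000829, and adjusted p = 0.0362 with an estimated correlation).

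Berberine bridge enzyme-like genes, a family with members that oxidise cell wall oligosaccharides, included 3 of 10 higher in edr1 at 18 h, and 4 when adjusted over the list alone, although the list did not pass (adjusted p = 0.0941). AT1G26420 was higher by 1.9 at 0 h (adjusted p = 0.014) and AT1G26380 by 1.74 at 18 h. Of 15 cytochrome P450 genes with CYP symbols 3 were higher in edr1 than in Col-0 at 18 h, 4 when adjusted over the list alone (adjusted p = 0.0342, and adjusted p = 0.574 with an estimated correlation). Glycosyltransferase genes with UGT symbols, 25 in all, were lower in the interaction at 96 h, with 1 called and 6 when adjusted over the list alone, but their median was -0.13 and turned to 0.11 on the deposited values (adjusted p = 0.0375, and adjusted p = 0.0965 with an estimated correlation). Of 69 plastid-encoded genes 0 were called between genotypes at 96 h, with a median of -0.12 (adjusted p = 0.0298, and adjusted p = 0.79 with an estimated correlation), and 18 fell in edr1 from 0 to 96 h (adjusted p = 0.0401, and adjusted p = 0.852 with an estimated correlation). AT5G26270 was the 1 probe set of 14892 with 2 separate levels in a scan for a gap over 2.5, a high level over 7 in more than 2 arrays and both levels within a group, and was high in 7 of 16 Col-0 arrays; what makes the 2 levels, differences in sequence or seed stock included, was not tested.

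Time of day of the harvest was examined as a reason why most probe sets change by 36 h in both genotypes. Counted from inoculation, 96 h falls at the nominal hour of 0 h and 36 h does not. The evening clock gene GI was nevertheless higher at 96 h than at 0 h in edr1 (9.09 against 7.68, limma adjusted p = 0.0018). An equal clock phase at 0 h and 96 h was therefore not shown. If time of day were the reason, the changes should be mostly gone at 96 h. Over 2884 probe sets called at least 2-fold in Col-0 at 36 h, the median ratio of the edr1 change at 96 h to that at 36 h was 0.19 (quartiles -0.05 to 0.43), and 0.23 over all called, which is consistent with time of day. A transient response to the fungus would give the same ratio, and without uninoculated plants at 36 h it is not excluded.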
